A study of Mus musculus with 28 samples.

How the data were processed

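Total RNA of mouse cells of strain 129SvEv was measured on Affymetrix whole-transcript expression arrays, with 28 arrays in 12 groups. Cells that were wild type or lacked topoisomerase IIβ (Top2β) were collected as embryonic stem (ES) cells, as neuronal progenitor (NP) cells and at the stages the labels call TN day 2 and TN day 6. The labels do not spell out TN. Each genotype had 2 arrays at the ES, NP and TN day 2 stages and 3 arrays at TN day 6. In a second experiment, cells at TN day 5 had received DMSO or the topoisomerase II inhibitor ICRF-193, with 2 arrays each. In the last experiment, glutamatergic neurons of the cortex of embryonic day 16.5 had received DMSO or ICRF-193, with 3 arrays each. The labels put one treatment description on all samples, 50 µM ICRF-193 or DMSO, renewed every 24 h between TN days 2 and 5; whether the cortical neurons were treated over those days is not stated. The labels do not say whether replicates were separate cultures or animals. The p-values measure only the spread between arrays of a group, pooled for each gene over all 12 groups. They do not measure the spread of the compared groups alone.

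The deposited table held one log2 expression value for each of 35556 probe sets and 28 arrays, made with oligo 1.14.0 per the submitters' processing notes. The summarization method, background correction and logarithm base are not given in the sources used here. The values lay between 1.963 and 13.99 and were read as base 2 from that range, so each log2 fold change rests on that reading. No further normalization was applied. The array medians were 6.33 and 6.30 in wild-type and 6.26 and 6.35 in knockout ES cells, 6.24 and 6.30 in wild-type and 6.26 and 6.22 in knockout NP cells, and 6.28 and 6.31 in wild-type and 6.35 and 6.32 in knockout cells at TN day 2. At TN day 6 they were 6.26, 6.25 and 6.30 in wild-type and 6.22, 6.28 and 6.29 in knockout cells. At TN day 5 they were 6.38 and 6.34 with DMSO and 6.43 and 6.41 with ICRF-193. In cortical neurons they were 6.12, 6.15 and 6.15 with DMSO and 6.27, 6.24 and 6.26 with ICRF-193. The precision is limited by the number of arrays.

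Probe sets were matched to genes with the probe annotation supplied for the table. Of the probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 had no entry; only the first kind was used. Of the 999 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which gave 19938 genes. A genomic span, from transcript start to transcript end in the RefSeq annotation of GRCm38.p6, was found for 19856 of them (99.6%). The files name no genome build, so gene positions are not given. Whether the Top2b probe set lies in the deleted part of the gene is not known from the files.

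A linear model with 12 group means was fitted to all 28 arrays with limma 3.58.1 in R 4.3.3, with 16 residual degrees of freedom and 4.87 prior degrees of freedom. The moderated statistics of limma were two-sided, and the p-values were adjusted by the method of Benjamini and Hochberg (BH) over the 19938 genes of each comparison; an adjusted p under 0.05 was the threshold for a call. The 6 main comparisons were knockout against wild type at each of the 4 stages and ICRF-193 against DMSO in each of the other experiments. Another 3 comparisons followed wild-type cells from ES to NP, from NP to TN day 2 and from TN day 2 to TN day 6. Differences between effects were tested with 4 interaction contrasts. No main comparison shared an array with another. Errors of log2 fold changes are standard errors (SE) of the model, and n is the number of arrays.

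The 25 gene lists, of 568 symbols, of which 525 were measured, covered topoisomerases, pluripotency, neural progenitor and radial glia, pan-neuronal, glutamatergic neuron, GABAergic neuron, neural crest and peripheral neuron, astrocyte, oligodendrocyte lineage, microglia, endothelial and mural cell, mesenchymal and fibroblast, early mesoderm, endoderm, cell cycle, p53 target, neurotrophins and receptors, axon guidance, neuronal adhesion, voltage-gated ion channel, very long gene, immediate early, ATF4 and ER stress, interferon-stimulated and Hox genes. The lists, the comparisons, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, apart from the crossed block named at the end of the methods and the tests named in the closing part. Each list was tested with camera of limma at a preset inter-gene correlation of 0.01, and the 150 tests of the main comparisons were adjusted together. An estimated correlation and fry were the alternatives. Calls were also counted with adjustment over the list alone. A list of very long genes and several lists of neuronal genes overlap in what they measure, since 31 of 40 adhesion genes, 28 of 36 ion channel genes, 29 of 39 axon guidance genes and 11 of 21 glutamatergic genes span over 100 kb.

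Gene span was compared with expression in 2 ways. Spearman's rho across genes was computed between span and log2 fold change. The share of genes over 100 kb among the calls of 1 direction was compared with that among genes without a call by two-sided Fisher's exact test. Overlaps of calls were tested for the 15 pairs of main comparisons in each of 4 combinations of direction, 60 tests in all, with Fisher's exact test and BH adjustment. Genes are not independent replicates in any of these.

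Named genes were the 10 with the largest change in each direction among calls whose groups did not overlap, together with Top2b, Top2a, Ngfr, Ntrk2 and Ntrk3 in every comparison and up to 4 genes with the largest called change from each list, or up to 2 with the smallest p where none was called. Symbols that only number a clone, prediction or family member (2877 of the genes) could be left unnamed.

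Alternatives were a fit of only the arrays compared, replicate number as a block, a filter on genes whose group means stayed under 6.29 (the median of all values), quantile normalization, centring of each array on its median, a prior with trend and robust estimation, array weights, the mean over a gene's probe sets, and each array left out in turn. Where an array was left out of a pair, the remaining one is assumed to vary like the other groups. Overlaps were also counted with a fold of 1.5 or more, and span was also compared at 50 and 200 kb. A crossed block for NP cells was added after the data were seen. The method was tested on simulated data: with random values of each gene's own spread, no group differences and known changes added to a set of genes, the share of 2-fold changes that was called ran from 80.6% in the comparison at TN day 2 to 98.5% at TN day 6, and of 1.5-fold changes from 37.3% at TN day 5 to 67.2% at TN day 6. The simulated changed list was called in each of the 6 comparisons, with 0 other lists called by camera. Simulated genes varied independently of each other and had the same spread in every group. The simulation therefore cannot show how the list test behaves with correlated genes or with groups of unequal spread.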

Results

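Expression was measured on 28 arrays, from ES cells through neuronal differentiation in the presence or absence of Top2β and in neurons given the topoisomerase II inhibitor ICRF-193. ES cells, NP cells and cells at TN day 2 had 2 wild-type and 2 knockout arrays each, and TN day 6 had 3 and 3. DMSO and ICRF-193 had 2 arrays each at TN day 5 and 3 each in cortical neurons. The array medians lay between 6.12 and 6.43. Genes are identified by symbol, and log2 fold changes are given ± SE of the limma model, with adjusted p-values over all 19938 genes. The correlation between arrays of one group was 0.967 for the knockout ES pair and between 0.990 and 0.997 in the other groups. The first principal component of all values held 58.4% of the variance and the second 14.1%. The median SE of a fold change was 0.14 for pairs of arrays and 0.12 for groups of 3. No label names an array batch. For each gene named with a call, every array of one group lay above every array of the other.

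The first question was how the deleted gene itself was expressed. In wild-type cells Top2b (probe set 10412844) rose along differentiation, by 1.40 ± 0.24 from ES to NP cells (adjusted p = 5.5e-05) and by 2.24 ± 0.24 from NP cells to TN day 2 (adjusted p = 6.7e-08), each with n = 2 and 2. In knockout cells its signal was lower at every stage. It fell by 1.29 ± 0.24 in ES cells (adjusted p = 0.018) and by 2.31 ± 0.24 in NP cells (adjusted p = 2.9e-05). It fell by 2.41 ± 0.24 at TN day 2 (adjusted p = 1.9e-06) and by 2.31 ± 0.20 at TN day 6 (adjusted p = 3.5e-08). Wild-type means were 7.74 ± 0.30, 9.14 ± 0.05, 11.4 ± 0.04 and 11.2 ± 0.09 (SD, n = 2, 2, 2 and 3). Knockout means were 6.45 ± 0.94, 6.83 ± 0.08, 8.97 ± 0.03 and 8.91 ± 0.20, and every knockout array lay below every wild-type array of its stage. The call in ES cells ended without wild-type replicate 1. It also ended with only the arrays compared (limma adjusted p = 0.93) and with array weights (0.615). The 2 knockout ES arrays stood apart, at 7.11 and 5.79. Top2b was not called after ICRF-193 at TN day 5 (-0.19 ± 0.24, adjusted p = 0.68) or in cortical neurons (0.12 ± 0.20, adjusted p = 0.69). Its paralog Top2a (probe set 10390707) was not called in knockout ES cells (-0.23, adjusted p = 0.67) or NP cells (-0.04, adjusted p = 1) or at TN day 2 (0.46 ± 0.21, adjusted p = 0.20). At TN day 6 it was higher in knockout cells by 1.78 ± 0.17 (adjusted p = 3.1e-07). After ICRF-193 it fell by 2.45 ± 0.21 at TN day 5 (adjusted p = 6.1e-08) and by 2.57 ± 0.17 in cortical neurons (adjusted p = 3.1e-10).

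**Figure D1:**
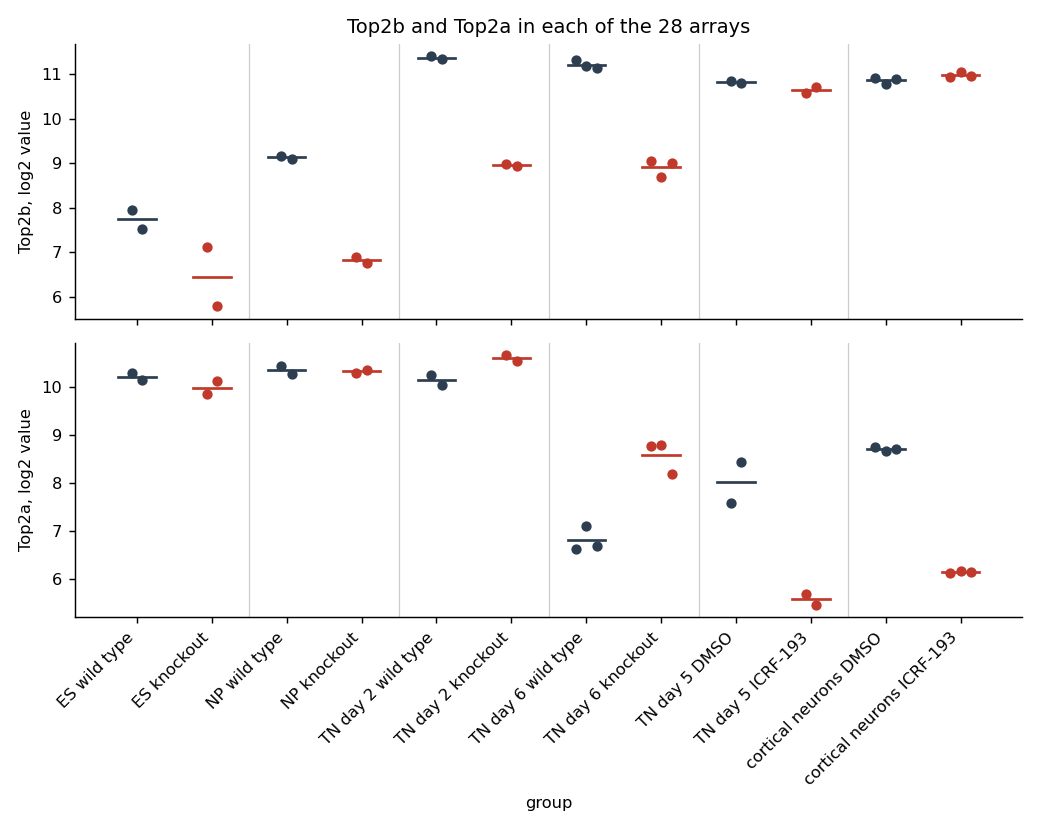
The log2 expression value of Top2b (upper panel) and Top2a (lower panel) is plotted for each of the 28 arrays by group; dark points are wild-type or DMSO arrays, red points knockout or ICRF-193 arrays, and lines are group means. Top2b fell by 2.31 in knockout cells at TN day 6, where Top2a rose by 1.78.

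The wild-type arrays describe the differentiation against which the knockout is set. From ES to NP cells 4329 genes rose and 4893 fell. Quantile normalization gave 5136 and 4382, and median centring 4952 and 4412, so which direction holds the majority depends on the scaling. Pou5f1 fell by 5.97 ± 0.23 (adjusted p = 2.1e-14), Nanog by 4.81 ± 0.22 and Tdgf1 by 6.21 ± 0.30. Of 25 pluripotency genes 24 fell and none rose (camera adjusted p = 2.14e-20; adjusted p = 0.0929 with an estimated correlation). Dcx rose by 4.55 ± 0.12, Fabp7 by 4.92 ± 0.52 and Hoxa5 by 5.03 ± 0.22. In all, 21 of 28 Hox genes rose with 0 falling (adjusted p = 2.36e-15; adjusted p = 0.161 with an estimated correlation). From NP cells to TN day 2, 4299 genes rose and 5310 fell. Gap43 rose by 3.33 ± 0.12, Chl1 by 4.39 ± 0.18 and Gria2 by 4.21 ± 0.20. Of 29 pan-neuronal genes 27 rose and 1 fell (adjusted p = 1.43e-14), a call that held with an estimated correlation (adjusted p = 0.0403). Krt18 fell by 4.08 ± 0.23 and Aurkb by 2.85 ± 0.15. From TN day 2 to TN day 6, 3324 genes rose and 2366 fell, with 2669 and 1470 without TN day 2 replicate 1 and 2203 and 2085 without replicate 2. All 31 cell cycle genes fell, with a median of -1.74 (adjusted p = 6.68e-43; with an estimated correlation 0.0403), among them Bub1 by 3.32 ± 0.23 and Mki67 by 3.06 ± 0.21. Slc17a6, a vesicular glutamate transporter, rose by 3.19 ± 0.25, and 12 of 21 glutamatergic genes rose while 1 fell (adjusted p = 2.4e-06; with an estimated correlation 0.0276). The progenitor genes Pax6 (-2.08 ± 0.27) and Gli3 fell, with 14 of 21 progenitor and radial glia genes lower and none higher.

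Knockout and wild-type cells were next compared as ES cells, n = 2 each, which asks whether the loss of Top2β acts before differentiation. Psors1c2 fell by 1.67 ± 0.14 from a wild-type mean of 7.69 (adjusted p = 1.6e-06) and Nxf3 by 1.38 ± 0.14 from 5.4 (adjusted p = 3.9e-05). Usp26 fell by 1.77 ± 0.27 (adjusted p = 0.0033), and without wild-type replicate 1 its call ended (adjusted p = 0.0536). The neurofilament gene Nefl fell by 0.87 ± 0.15 (adjusted p = 0.012) and Gad2 rose by 0.73 ± 0.13 (adjusted p = 0.015). C1qc and Irx3 rose by 1.04 ± 0.22 and 1.004 ± 0.21. None of these 4 passed without wild-type replicate 1, without wild-type replicate 2 or without knockout replicate 1 (adjusted p from 0.05 to 0.529). In all, 70 genes changed, 17 higher and 53 lower, and 4 of the higher and 15 of the lower ones changed 2-fold or more. With each array centred on its median the split was 5 higher and 46 lower. The count hung on single arrays: it was 5 without wild-type replicate 1, 32 without wild-type replicate 2 and 5018 without knockout replicate 2 (2817 higher and 2201 lower, which turns the majority). With only the 4 ES arrays, or with array weights, limma called 0 genes, against 2995 at an unadjusted p under 0.05 in the fit of all arrays. None of the 23 named genes with a call kept it in every setting.

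Hox genes were higher as a list in knockout ES cells (median 0.52, adjusted p = 3.49e-12; adjusted p = 0.17 with an estimated correlation), with 0 of 28 called over all genes and 12 higher when adjusted over the list alone. Hoxd3 stood at 0.67 ± 0.15 (adjusted p = 0.053). Pluripotency genes were lower (median -0.43, adjusted p = 3.33e-07; adjusted p = 0.327 with an estimated correlation), with 0 of 25 called and 5 lower when adjusted over the list alone. Zfp42 stood at -1.29 ± 0.38 (adjusted p = 0.15). The lists of mesenchymal and fibroblast genes (median 0.64, adjusted p = 0.00016; adjusted p = 0.514 with an estimated correlation) and early mesoderm (median 0.59, adjusted p = 0.0038; adjusted p = 0.511 with an estimated correlation) were higher. So were those of endoderm (0.43, adjusted p = 0.0013; adjusted p = 0.287 with an estimated correlation) and microglia (0.40, adjusted p = 0.00033; adjusted p = 0.217 with an estimated correlation). With adjustment over the list alone 1, 1, 6 and 6 of their genes rose. The cell cycle list was lower (-0.18, camera adjusted p = 0.0012, or 0.67 with an estimated correlation). The axon guidance list was higher (0.25, camera adjusted p = 0.0028, or 0.564 with an estimated correlation). No gene of either list was called over all genes. Of these 8 lists, the Hox, pluripotency, mesenchymal, endoderm, microglia and cell cycle calls ended without knockout replicate 1 (adjusted p = 0.279, 0.218, 0.387, 0.38, 0.0676 and 0.213), where the pluripotency and mesenchymal lists also changed direction. The early mesoderm and axon guidance lists were then lower rather than higher (adjusted p = 0.002 and 0.0021). Of the 8 genes of the topoisomerase list 1 fell, the deleted gene Top2b itself. The list was lower (camera adjusted p = 0.013, or 0.204 with an estimated correlation), a call that ended without wild-type replicate 1 and without knockout replicate 2. The lists of very long genes (0.15, adjusted p = 0.012; adjusted p = 0.595 with an estimated correlation), endothelial and mural cells (0.40, adjusted p = 0.038; adjusted p = 0.391 with an estimated correlation) and GABAergic neurons (0.07, adjusted p = 0.044; adjusted p = 0.297 with an estimated correlation) were higher. Each lost its call without knockout replicate 1 (0.828, 0.676 and 0.12), the endothelial list with a turn in direction. The last 2 were also lost with quantile normalization (0.081 each), and without wild-type replicate 2 (0.0953 and 0.107). The very long list was also lost without wild-type replicate 1 (0.351) and the GABAergic list without knockout replicate 2 (0.231) and with the replicate block (0.0521), and the endothelial list with only the arrays compared (0.0795).

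In NP cells, n = 2 each, the same comparison found 125 changed genes, 76 higher and 49 lower, of which 29 and 7 changed 2-fold or more. The adhesion receptor gene Adgrg2 rose by 1.89 ± 0.24 from a wild-type mean of 5.49 (adjusted p = 0.00031) and the kinase gene Stk26 by 1.51 ± 0.18 from 7.47 (adjusted p = 0.00018). Sv2a, which encodes a synaptic vesicle protein, rose by 1.06 ± 0.10 (adjusted p = 8.1e-06), and the potassium channel genes Kcne3 and Kcnd2 rose by 1.33 ± 0.15 and 1.19 ± 0.16. The prolactin family gene Prl7b1 rose by 1.30 ± 0.14. Beside Top2b, Crygd fell by 1.25 ± 0.18 (adjusted p = 0.00092), Cyp2d22 by 1.19 ± 0.15 and Agtr1a by 1.11 ± 0.12. The very long adhesion gene Nrxn3 fell by 1.06 ± 0.16 (adjusted p = 0.0015) and Th, for tyrosine hydroxylase, by 1.01 ± 0.15. These 12 of the 32 named genes with a call kept it in every setting. The count was 72 without wild-type replicate 1, 60 without wild-type replicate 2 (23 higher and 37 lower, which turns the majority) and 37 without either knockout array. It was 201 with only the 4 arrays compared and 251 with array weights.

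Endothelial and mural genes were higher as a list in knockout NP cells (median 0.57, adjusted p = 2.8e-10), also with an estimated correlation (adjusted p = 0.015). Of 15 genes 1, Cldn5 (0.73 ± 0.15, adjusted p = 0.022), was called, and 10 rose and 1 fell when adjusted over the list alone. The call for Cldn5 ended when any of the 4 arrays was left out and with the replicate block (limma adjusted p = 0.0571). Pluripotency genes were lower (median -0.26, adjusted p = 0.00015; adjusted p = 0.504 with an estimated correlation). Of 25 only Utf1 fell (-0.95 ± 0.15, adjusted p = 0.0018), a call that ended without knockout replicate 2 (0.0692). Astrocyte genes were lower (-0.14, adjusted p = 0.0026; adjusted p = 0.0636 with an estimated correlation), with 1 of 14 called and 2 lower when adjusted over the list alone. That gene, Slc1a3 (-1.07 ± 0.23, adjusted p = 0.027), was also the 1 called of 21 progenitor and radial glia genes, a lower list (-0.21, adjusted p = 0.0094; adjusted p = 0.541 with an estimated correlation). The call for Slc1a3 ended when any of the 4 arrays was left out. It also ended with the replicate block (limma adjusted p = 0.0729) and the crossed block (0.0682). The call for the progenitor list ended without wild-type replicate 1 or knockout replicate 1. GABAergic genes were lower (-0.11, adjusted p = 0.0094; adjusted p = 0.173 with an estimated correlation) except without wild-type replicate 2 (0.198), with 0 of 13 called by limma. Neurotrophins and receptors (-0.12, adjusted p = 0.037; adjusted p = 0.389 with an estimated correlation) and interferon-stimulated genes (-0.18, adjusted p = 0.044; adjusted p = 0.391 with an estimated correlation) were lower with 0 of 15 and 0 of 14 called. They lost the call without wild-type replicate 1 (0.2 and 0.31) or knockout replicate 1 (0.0751 and 0.14). The interferon list also lost it with quantile normalization (0.0816).

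At TN day 2, n = 2 each, knockout and wild-type cells differed in 2284 genes, 1094 higher and 1190 lower, and of those that changed 2-fold or more 360 were higher and 114 lower. Nrg3 fell by 2.21 ± 0.15 from a wild-type mean of 7.97 (adjusted p = 8.2e-09), Ncam2 by 2.15 ± 0.15 from 8.63 (adjusted p = 2.2e-08) and Nrxn3 by 2.01 ± 0.16 from 9.63 (adjusted p = 1.3e-07). Mdga2, Erbb4, Tenm1 and Ctnna2 fell by 1.93 ± 0.16, 1.89 ± 0.17, 1.87 ± 0.26 and 1.87 ± 0.15. Among higher genes, the receptor gene Kdr rose by 3.51 ± 0.48 from 6.08 (adjusted p = 7e-05) and Stk26, also higher in NP cells, by 3.43 ± 0.18 from 4.74 (adjusted p = 3.5e-10). Podxl rose by 2.97 ± 0.36 and the signalling gene Wnt1 by 2.84 ± 0.27 (adjusted p = 1e-06). Prss35 and Calcr rose by 3.03 ± 0.44 and 2.63 ± 0.34. The count was 714 without wild-type replicate 1 (436 higher), 504 without knockout replicate 2 (267 higher) and 315 with only the 4 arrays compared (192 higher). In these 3 settings, and without knockout replicate 1 (1147 of 2153 higher), the majority turned. Of the 87 named genes with a call, 28 kept it in every setting; the genes of this paragraph are among them.

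Cell cycle genes were higher in knockout cells at TN day 2 (median 0.48, adjusted p = 1.1e-16; adjusted p = 0.173 with an estimated correlation): 15 of 31 rose and 0 fell, or 25 when adjusted over the list alone. Mcm6 rose by 0.82 ± 0.13 (adjusted p = 0.00025). Pan-neuronal genes were lower (-0.48, adjusted p = 8.5e-12; adjusted p = 0.0568 with an estimated correlation), with 16 of 29 falling, none rising and 22 lower when adjusted over the list alone. Syt1 fell by 1.01 ± 0.15 (adjusted p = 0.00015). Of 40 adhesion genes 22 fell and 0 rose, 25 when adjusted over the list alone (-0.54, adjusted p = 2.2e-16; adjusted p = 0.108 with an estimated correlation). Among them were Cntn6 (-1.71 ± 0.22), Cdh13 (-1.46 ± 0.17) and Cdh10 (-1.40 ± 0.14). Of 52 very long genes 24 fell and 1 rose, 30 and 1 when adjusted over the list alone (-0.50, adjusted p = 2.6e-15; adjusted p = 0.0737 with an estimated correlation). Of 36 ion channel genes 11 fell and 1 rose, 15 and 2 when adjusted over the list alone (-0.35, adjusted p = 3.7e-05; adjusted p = 0.279 with an estimated correlation). Cacna2d3 fell by 1.58 ± 0.14. Of 39 axon guidance genes 11 fell and 3 rose, 16 and 4 when adjusted over the list alone (-0.42, adjusted p = 0.0019; adjusted p = 0.542 with an estimated correlation). Epha5 (-1.69 ± 0.21) and Ephb1 (-1.38 ± 0.16) were lower. Of 21 glutamatergic genes 5 fell, 7 when adjusted over the list alone with 1 higher (-0.31, adjusted p = 0.0019; adjusted p = 0.0737 with an estimated correlation). Grik2 fell by 1.20 ± 0.21.

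The list of p53 targets was higher at TN day 2 (median 0.45, adjusted p = 1.8e-09; adjusted p = 0.0737 with an estimated correlation): 13 of 24 rose and 0 fell, with 15 higher and 1 lower when adjusted over the list alone. Perp rose by 1.99 ± 0.25 and Tnfrsf10b by 1.78 ± 0.30, calls that ended with only the arrays compared (adjusted p = 0.0508 and 0.115). Mesenchymal genes were higher (1.32, adjusted p = 8.3e-08; adjusted p = 0.331 with an estimated correlation), with 8 of 16 rising and 13 when adjusted over the list alone. Tagln rose by 2.33 ± 0.46, except with only the arrays compared (adjusted p = 0.126) and without wild-type replicate 1 (0.0978) or knockout replicate 2 (0.0797). The ATF4 and ER stress list was higher with 4 of 20 rising (0.18, adjusted p = 0.0018; adjusted p = 0.297 with an estimated correlation) but not without knockout replicate 2 (0.112). The endoderm list was higher with 3 of 14 rising and 4 when adjusted over the list alone (0.24, adjusted p = 0.01; adjusted p = 0.391 with an estimated correlation) but not without knockout replicate 1 (0.0602). Neurotrophins and receptors were lower (-0.25, adjusted p = 0.00036; adjusted p = 0.122 with an estimated correlation), with 5 of 15 falling and 6 when adjusted over the list alone. Sorcs3 fell by 1.56 ± 0.20, Ntrk3 by 1.33 and Gfra1 by 1.03 ± 0.12. The neurotrophin receptor gene Ngfr fell by 0.60 ± 0.14 (adjusted p = 0.0075), except with only the arrays compared (0.0954) and without wild-type replicate 1 (0.188) or knockout replicate 2 (0.0909).

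At TN day 6, n = 3 each, 2030 genes differed between knockout and wild type, 1072 higher and 958 lower, and 211 and 142 of them changed 2-fold or more. Tac1, the precursor of substance P, fell by 3.85 ± 0.18 from a wild-type mean of 10.2 ± 0.06 (SD, adjusted p = 1.2e-11). The neurite growth gene Nrn1 fell by 2.89 ± 0.30 from 8.98 ± 0.03 (adjusted p = 7.2e-07) and Nrg3 by 2.50 ± 0.12 from 9.21 ± 0.07 (adjusted p = 1.2e-11). The Wnt modulator gene Sfrp2 rose by 3.36 ± 0.18 from 7.14 ± 0.17 (adjusted p = 2.5e-11), and the progenitor genes Pax6 and Id3 by 2.32 ± 0.24 (adjusted p = 5.4e-07) and 2.27 ± 0.16 (adjusted p = 2.3e-09). Cntnap5a, Lpl, Adgrl3, Robo2 and Galnt13 fell by 2.73 ± 0.18, 2.65 ± 0.16, 2.46 ± 0.14, 2.37 ± 0.34 and 2.34 ± 0.18. Srgn, Cyp26a1, Pdgfra, Lamb1 and Islr2 rose by 2.73 ± 0.39, 2.38 ± 0.50, 2.20 ± 0.41, 2.16 ± 0.33 and 2.13 ± 0.11. Of the 91 named genes with a call 78 kept it in every setting, those of this paragraph included, and leaving out single arrays gave between 1394 and 1840 calls. The majority turned without wild-type replicate 1 (740 higher and 793 lower) and without knockout replicate 2 (664 and 730). Array weights gave 3816.

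Very long genes fell as a list at TN day 6 (median -0.94, adjusted p = 1.5e-48), also with an estimated correlation (adjusted p = 0.002): 40 of 52 fell and 0 rose, or 43 and 1 when adjusted over the list alone. Dpp10 fell by 2.05 ± 0.14 (adjusted p = 2.2e-09) and Dcc by 1.93 ± 0.14 (adjusted p = 5e-09). Of 21 glutamatergic genes 9 fell and 0 rose, 11 and 1 when adjusted over the list alone (-0.26, adjusted p = 1.3e-06; with an estimated correlation 0.0082). Among them were Grik2 (-2.31 ± 0.17), Slc17a6 (-1.96 ± 0.23) and Grin2b (-1.02 ± 0.13). Cell cycle genes moved the other way, with 29 of 31 higher and 0 lower, 30 when adjusted over the list alone (1.001, adjusted p = 1.5e-34; adjusted p = 0.0568 with an estimated correlation). Bub1 rose by 1.68 ± 0.20, Mcm3 by 1.49 ± 0.18 and Kif11 by 1.47 ± 0.20. Of 21 progenitor and radial glia genes 12 rose and 1 fell, 16 and 1 when adjusted over the list alone (0.66, adjusted p = 6.1e-11; adjusted p = 0.107 with an estimated correlation). Sox2 rose by 1.57 ± 0.22, Hes1 by 1.21 ± 0.23 and Slc1a3 by 1.19 ± 0.19. Adhesion genes fell, 20 of 40 against 1 higher, 25 and 1 when adjusted over the list alone (-0.54, adjusted p = 1.7e-19; adjusted p = 0.0737 with an estimated correlation). Cdh13 fell by 2.11 ± 0.14 and Ntm by 1.74 ± 0.18.

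Endoderm genes were higher at TN day 6, 4 of 14 with 0 lower and 6 when adjusted over the list alone (median 0.59, adjusted p = 9.9e-05; adjusted p = 0.19 with an estimated correlation). Lama1 rose by 1.75 ± 0.24. Of 24 p53 targets 5 rose and 0 fell, 8 when adjusted over the list alone (0.19, adjusted p = 0.0022; adjusted p = 0.366 with an estimated correlation). Ccng1 rose by 0.48 ± 0.10. Of 14 astrocyte genes 4 rose, 6 when adjusted over the list alone (0.06, adjusted p = 0.013; adjusted p = 0.108 with an estimated correlation). Fgfr3 rose by 1.66 ± 0.18 and Gja1 by 1.48 ± 0.20. The list call ended with only the arrays compared (0.0558). Ion channel genes were lower, 7 of 36 against 3 higher, 10 and 3 when adjusted over the list alone (-0.19, adjusted p = 0.0094; adjusted p = 0.515 with an estimated correlation). Kcnd2 fell by 1.33 ± 0.13 and Kcnip1 rose by 1.36 ± 0.12. Pan-neuronal genes were divided, 5 of 29 lower and 3 higher, 9 and 3 when adjusted over the list alone (-0.09, adjusted p = 0.025; adjusted p = 0.537 with an estimated correlation). Syt1 fell by 0.79 ± 0.12 while Nefm rose by 1.02 ± 0.14. That call ended without wild-type replicate 1 (0.0517) or knockout replicate 2 (0.0785). Axon guidance genes were lower, 8 of 39 against 5 higher, 12 and 5 when adjusted over the list alone (-0.13, adjusted p = 0.027; adjusted p = 0.737 with an estimated correlation). They did not pass without wild-type replicate 2 (0.0518) or knockout replicate 3 (0.0649). Pluripotency genes were higher, 4 of 25 and 5 when adjusted over the list alone (0.09, adjusted p = 0.044; adjusted p = 0.751 with an estimated correlation). Esrrb rose by 1.10 ± 0.21. The pluripotency call ended with quantile normalization (0.0726) and without wild-type replicate 1 (0.053), wild-type replicate 2 (0.0885) or knockout replicate 2 (0.0595). The neural crest and peripheral neuron list passed with camera in none of the 6 comparisons; fry called it lower at TN day 2 (adjusted p = 0.0131). At TN day 6, 5 of its 14 genes rose and 2 fell, 6 and 4 when adjusted over the list alone (adjusted p = 0.62). Prph rose by 1.31 ± 0.10 and Tfap2b fell by 2.04 ± 0.16. Ngfr rose by 0.64 ± 0.12 (adjusted p = 0.0006) and Ntrk3 fell by 1.20 ± 0.12.

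**Figure D2:**
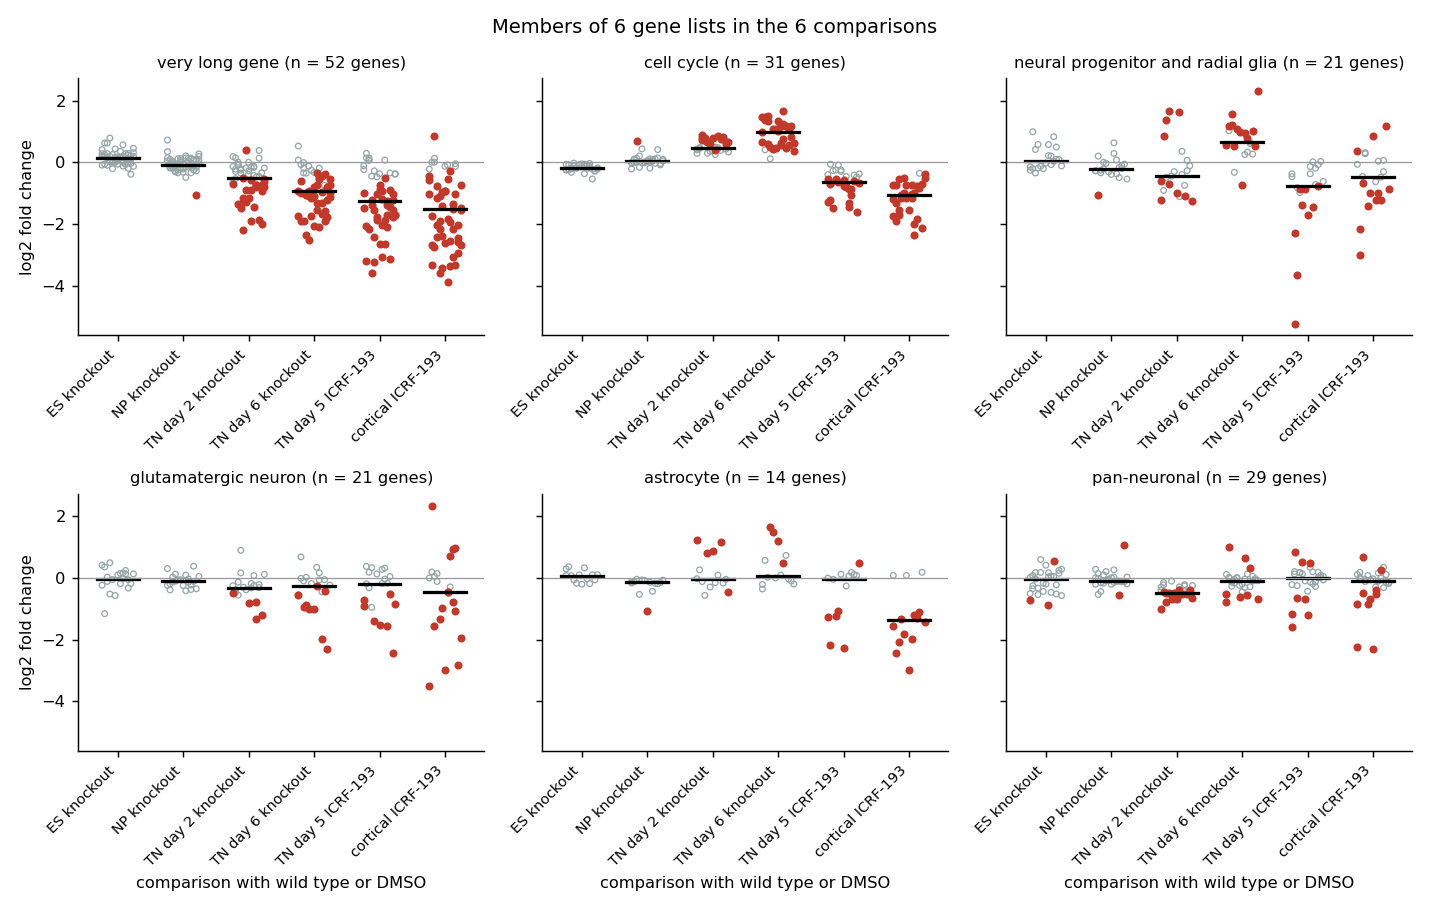
Each dot is a gene of the list named above its panel, placed by its log2 fold change (y axis) in each of the 6 comparisons (x axis); filled red dots were called, open grey dots were not, and bars are medians. The median of very long genes at TN day 6 was -0.94, and that of cell cycle genes was 1.001 in knockout cells and -0.65 after ICRF-193 at TN day 5.

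ICRF-193 against DMSO at TN day 5, n = 2 each, asks what blocking topoisomerase II does in differentiating cells that carry the enzyme. It changed 1772 genes, 501 higher and 1271 lower, of which 24 and 318 changed 2-fold or more. Fabp7, a radial glia gene, fell by 5.23 ± 0.52 from a DMSO mean of 10.6 ± 0.98 (SD, adjusted p = 4.4e-07) and Sox2 by 3.67 ± 0.27 from 9.01 ± 0.44 (adjusted p = 3.5e-09). Adgrl3 fell by 4.13 ± 0.17 from 10.6 ± 0.05 (adjusted p = 1e-12), Nrg3 by 3.25 ± 0.15 (adjusted p = 1.8e-12). Robo2 (-3.60 ± 0.42), Mdga2 (-3.37 ± 0.16), the transcription factor gene Ebf1 (-3.24 ± 0.17) and Ncam2 (-3.23 ± 0.15) also fell. Lmo3 rose by 1.39 ± 0.16 from 7.62 (adjusted p = 4.8e-06). The channel genes Asic4 and Chrna5 rose by 1.37 ± 0.13 and 1.36 ± 0.23, Insyn2a by 1.31 ± 0.10 (adjusted p = 1.2e-08) and Rph3a by 1.24 ± 0.15. Ngfr rose by 1.005 ± 0.14 (adjusted p = 5.1e-05), while Ntrk3 and Ntrk2 fell by 1.62 ± 0.14 and 1.33 ± 0.21. With each array centred on its median the split was 294 higher and 1579 lower. The count was 684 without DMSO replicate 2, 868 without ICRF-193 replicate 1, 385 with only the 4 arrays compared and 742 with array weights. Of 76 named genes with a call 54 kept it in every setting, those of this paragraph included.

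Very long genes fell as a list at TN day 5 (median -1.24, adjusted p = 2.3e-47), also with an estimated correlation (adjusted p = 0.002), with 37 of 52 falling, none rising and 42 lower when adjusted over the list alone. Dcc fell by 3.25 ± 0.17 and Ptprd by 3.21 ± 0.27. Glutamatergic genes fell, 8 of 21 and 9 when adjusted over the list alone (-0.19, adjusted p = 0.00028; with an estimated correlation 0.0474). Grik2 fell by 2.44 ± 0.21 and Grin2b by 1.54 ± 0.16. Of 31 cell cycle genes 19 fell and 0 rose, 24 when adjusted over the list alone (-0.65, adjusted p = 5.5e-17; adjusted p = 0.173 with an estimated correlation). Mki67 fell by 1.62 ± 0.23 and Mcm3 by 1.46 ± 0.22. Of 21 progenitor and radial glia genes 9 fell and 0 rose, 11 when adjusted over the list alone (-0.77, adjusted p = 2.7e-10; adjusted p = 0.11 with an estimated correlation). Of 40 adhesion genes 21 fell and 0 rose, 25 and 3 when adjusted over the list alone (-0.75, adjusted p = 5.6e-14; adjusted p = 0.129 with an estimated correlation). Cdh13 fell by 2.63 ± 0.17 and Cntn5 by 2.31 ± 0.23. Of 39 axon guidance genes 15 fell and 4 rose, 19 and 5 when adjusted over the list alone (-0.51, adjusted p = 1e-08; adjusted p = 0.226 with an estimated correlation), with Cxcr4 at -2.23 ± 0.36. ATF4 and ER stress genes fell, 4 of 20, with 7 lower and 1 higher when adjusted over the list alone (-0.34, adjusted p = 0.00013; adjusted p = 0.199 with an estimated correlation). Phgdh fell by 1.06 ± 0.15.

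Smaller list calls at TN day 5 hung on single arrays. Immediate early genes were lower, 4 of 20 against 1 higher, 6 and 1 when adjusted over the list alone (median -0.12, adjusted p = 0.022; adjusted p = 0.389 with an estimated correlation). Fos fell by 1.49 ± 0.19 and Nr4a1 by 1.44 ± 0.13. The list call ended without DMSO replicate 1 (0.0652) or ICRF-193 replicate 2 (0.123). Mesenchymal genes were lower, 2 of 16 (-0.65, adjusted p = 0.003; adjusted p = 0.633 with an estimated correlation), except without DMSO replicate 2 (0.143). Astrocyte genes were lower, 5 of 14 against 1 higher (-0.02, adjusted p = 0.026; adjusted p = 0.143 with an estimated correlation). Aldoc fell by 2.17 ± 0.27, and the list passed except without ICRF-193 replicate 2 (0.197). The topoisomerase list, which also holds Tdp1 and Tdp2, was lower (-0.16, camera adjusted p = 0.022, or 0.24 with an estimated correlation). The 2 of its 8 genes called were Top2a and Tdp1. The list call ended with quantile normalization (0.0936) and without ICRF-193 replicate 1. Microglia genes were higher, 1 of 13 (0.28, adjusted p = 0.038; adjusted p = 0.514 with an estimated correlation), except with quantile normalization (0.165) or without DMSO replicate 2 (0.245) or ICRF-193 replicate 1 (0.159). Syt1 fell by 1.58 ± 0.15 and Ncam1 by 1.22 ± 0.19 while Nefm rose by 0.83 ± 0.18, and the pan-neuronal list did not pass.

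In cortical neurons, n = 3 each, the same drug was compared with DMSO in cells that had not been made from ES cells. It changed 4664 genes, 1938 higher and 2726 lower, and 81 and 507 of them changed 2-fold or more. Mfge8 fell by 4.11 ± 0.25 from a DMSO mean of 10.96 ± 0.06 (SD, adjusted p = 4.3e-11). Adgrl3 fell by 3.95 ± 0.14 from 10.3 ± 0.07 (adjusted p = 1.9e-14) and Erbb4 by 3.87 ± 0.14 from 10.2 ± 0.07 (adjusted p = 2e-14). Nrg3 fell by 3.57 ± 0.12 from 9.09 ± 0.05 (adjusted p = 6.4e-15). Pdgfra, Ptprk, Scd1, Slco1c1 and the glutamate receptor gene Grm5 fell by 3.75 ± 0.41, 3.61 ± 0.14, 3.53 ± 0.23, 3.51 ± 0.14 and 3.49 ± 0.20. Chodl rose by 3.24 ± 0.11 from 5.29 ± 0.07 (adjusted p = 6.4e-15) and the calcium-binding protein gene Calb1 by 2.96 ± 0.21 from 7.52 ± 0.16 (adjusted p = 8.3e-10). Rasgrp1, Neurod1, Scg2 and Peg10 rose by 2.43 ± 0.13, 2.35 ± 0.35, 2.08 ± 0.14 and 2.07 ± 0.13. Ntrk2 and Ntrk3 fell by 2.14 ± 0.17 and 1.75 ± 0.12, and Ngfr was not called (0.25 ± 0.12, adjusted p = 0.12). The array medians were higher with ICRF-193. Centring each array on its median moved the median of all genes by -0.117 and the split to 792 higher and 4103 lower. A filter on dim genes put 30.6% of calls higher against 41.6%. The count was 7960 with only the 6 arrays compared and 8967 with array weights, there with 4621 higher and 4346 lower. Leaving out single arrays gave between 3321 and 3553 calls, between 1224 and 1370 of them higher, and 83 of 90 named genes, with all those called here, kept their calls in every setting.

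Very long genes fell as a list in cortical neurons (median -1.52, adjusted p = 4.8e-43), also with an estimated correlation (adjusted p = 0.0026): 43 of 52 fell and 1 rose, and the same number passed when adjusted over the list alone. Astrocyte genes fell, 11 of 14 with 0 higher, in both adjustments, over all genes and adjusted over the list alone (-1.37, adjusted p = 2.8e-12; with an estimated correlation 0.00035). Slc1a3 fell by 2.999 ± 0.19, Aldoc by 2.42 ± 0.22 and Aqp4 by 2.06 ± 0.10. Glutamatergic genes fell, 11 of 21 against 4 higher, also when adjusted over the list alone (-0.45, adjusted p = 0.00013; with an estimated correlation 0.0374). Grin2b fell by 2.99 ± 0.13 and Grik2 by 2.81 ± 0.17. Of 31 cell cycle genes 30 fell and 0 rose, 31 when adjusted over the list alone (-1.04, adjusted p = 2.6e-27; adjusted p = 0.0793 with an estimated correlation). Bub1 fell by 2.35 ± 0.20 and Mki67 by 2.14 ± 0.18. Of 40 adhesion genes 22 fell and 5 rose, 23 and 5 when adjusted over the list alone (-0.81, adjusted p = 2.2e-10; adjusted p = 0.204 with an estimated correlation). Cdh13 fell by 3.35 ± 0.14 and Cadm1 by 2.70 ± 0.09. Ion channel genes fell, 15 of 36 against 3 higher, 17 and 3 when adjusted over the list alone (-0.29, adjusted p = 2.5e-05; adjusted p = 0.266 with an estimated correlation). Cacna2d1 fell by 2.82 ± 0.17. Axon guidance genes fell, 15 of 39 against 2 higher, 16 and 4 when adjusted over the list alone (-0.26, adjusted p = 1.1e-05; adjusted p = 0.387 with an estimated correlation). Plxna4 fell by 2.69 ± 0.27. Microglia genes rose, 10 of 13 with none lower and 12 when adjusted over the list alone (0.64, adjusted p = 5.4e-06; adjusted p = 0.122 with an estimated correlation). C1qa rose by 1.0 ± 0.17 and Tyrobp by 0.77 ± 0.20.

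ATF4 and ER stress genes fell in cortical neurons, 9 of 20 and 10 when adjusted over the list alone (median -0.31, adjusted p = 0.00041; adjusted p = 0.236 with an estimated correlation). Slc7a11 fell by 1.36 ± 0.16. Oligodendrocyte lineage genes fell, 5 of 13, also when adjusted over the list alone (-0.14, adjusted p = 0.0038; adjusted p = 0.122 with an estimated correlation). Olig2 fell by 2.52 ± 0.17 and Olig1 by 2.28 ± 0.18. Pan-neuronal genes were lower, 8 of 29 against 2 higher, 9 and 2 when adjusted over the list alone (-0.10, adjusted p = 0.013; adjusted p = 0.506 with an estimated correlation). Ncam1 fell by 2.31 ± 0.16 and Syt1 by 2.24 ± 0.12. Progenitor and radial glia genes were lower, 9 of 21 against 3 higher, 11 and 3 when adjusted over the list alone (-0.48, adjusted p = 0.026; adjusted p = 0.613 with an estimated correlation). Fabp7 fell by 2.15 ± 0.43 and Nes by 1.41 ± 0.26. Quantile normalization ended the calls of the pan-neuronal list (0.0914) and the progenitor list (0.0779). The GABAergic list did not pass, with Gad2 higher by 0.80 ± 0.11 and Npy at -1.36 ± 0.12. Over the 6 comparisons and 150 list tests, 67 lists passed. With an estimated correlation 8 of these passed: the endothelial list in NP cells, the very long and glutamatergic lists at TN day 6, at TN day 5 and in cortical neurons, and the astrocyte list in cortical neurons.

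Gene span was examined because topoisomerase II relieves the twisting of DNA that transcription causes. Of the 19856 genes with a span, 2294 (11.6%) were longer than 100 kb. Among genes lower in knockout cells at TN day 6, 326 of 955 were that long (34.1%; odds ratio 4.66 with a 95% interval from 4.03 to 5.39, Fisher's exact p = 4.73e-84, BH-adjusted 7.1e-84 over 6 comparisons). At TN day 2 it was 373 of 1188 (odds ratio 4.23, 3.70 to 4.84, exact p = 4.97e-86, BH-adjusted 9.94e-86). After ICRF-193 it was 433 of 1270 at TN day 5 (4.69, 4.12 to 5.33, exact p = 2.76e-109, BH-adjusted 8.28e-109) and 742 of 2721 in cortical neurons (3.86, 3.48 to 4.27, exact p = 5.61e-136, BH-adjusted 3.37e-135). In NP cells 14 of 49 lower genes were long (3.09, 1.53 to 5.90, exact p = 0.000933, BH-adjusted 0.00112). In ES cells it was 8 of 53, which did not differ from genes without a call (1.36, 0.554 to 2.92, exact p = 0.39), with an odds ratio of 0.79 at a limit of 200 kb. Among higher calls the odds ratios of genes over 100 kb were 2.13 at TN day 2 (BH-adjusted p = 2.23e-17), 1.87 at TN day 6 (9.96e-12), 1.34 at TN day 5 (0.0407), 1.22 in cortical neurons (0.0219) and 2.22 in NP cells (0.0122). At a limit of 200 kb no excess among higher calls was found at TN day 6 (1.27, exact p = 0.113), TN day 5 (1.28, exact p = 0.257) or in cortical neurons (1.11, exact p = 0.459). It stayed at TN day 2 (1.96, exact p = 7.97e-07) and in NP cells (3.10, exact p = 0.00283). With dim genes removed, the excess of genes over 100 kb among higher calls in NP cells did not pass (1.83, exact p = 0.0616). Among lower calls the odds ratios at that limit were 8.93 at TN day 6, 9.51 at TN day 5, 7.48 in cortical neurons, 6.24 at TN day 2 and 5.25 in NP cells.

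Genes over 300 kb, of which there were 530, had median log2 fold changes of -0.23 at TN day 2, -0.25 at TN day 6, -0.45 after ICRF-193 at TN day 5 and -0.63 in cortical neurons, against 0.09 in ES cells and -0.05 in NP cells. The share of them called lower was 30.8%, 37.4%, 44.5% and 62.8% in the first 4 and 0.189% and 1.70% in ES and NP cells. Of the 6999 genes under 10 kb, 3.42%, 2.80%, 3.74% and 9.32% were lower in the same 4 comparisons. Over all genes the correlation of span with log2 fold change was -0.187 at TN day 5 and -0.191 in cortical neurons (Spearman's rho across genes, which are not independent replicates). It was -0.0455 at TN day 2, 0.0349 at TN day 6, 0.0462 in NP cells and 0.0326 in ES cells. With dim genes removed it was -0.117 at TN day 5 and -0.0879 in cortical neurons, and it turned to -0.0400 at TN day 6.

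**Figure D3:**
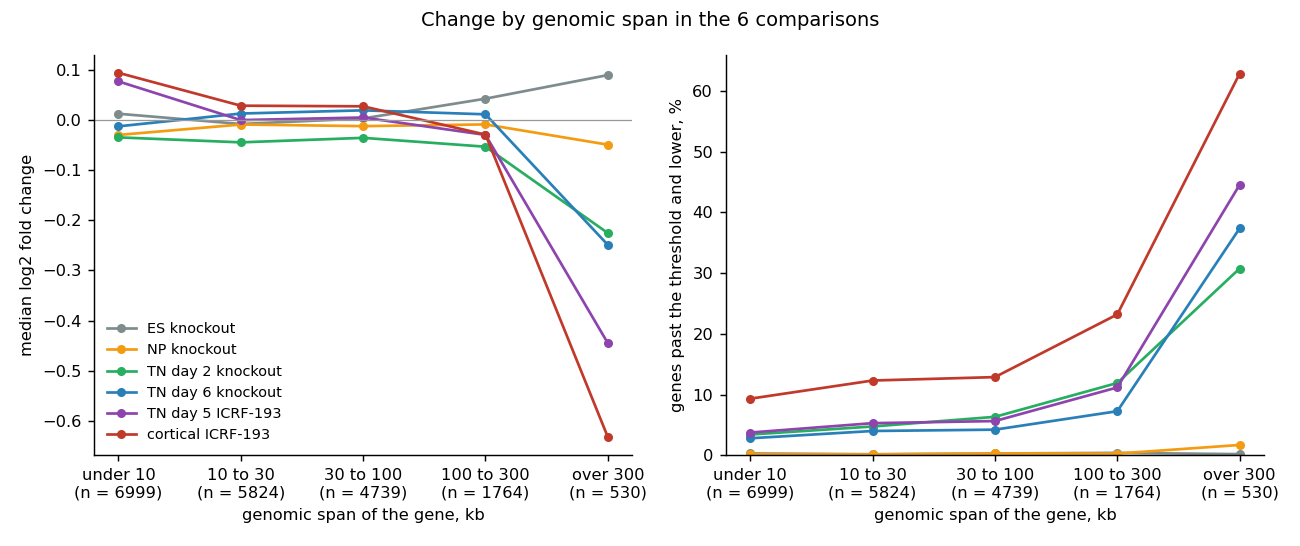
The left panel plots the median log2 fold change and the right panel the percent of genes called lower, each by class of genomic span (x axis, kb), with 1 coloured line for each of the 6 comparisons. In the class over 300 kb, 62.8% of genes were lower in cortical neurons after ICRF-193 and 37.4% in knockout cells at TN day 6.

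Whether the knockout and the inhibitor act on the same genes was asked from the overlap of calls. Knockout cells at TN day 6 and ICRF-193 cells at TN day 5 shared 312 lower genes, where 61.1 would be expected by chance (Fisher's exact p = 4.81e-144, BH-adjusted 1.44e-142 over 60 tests). They shared 100 higher genes (26.9 expected; exact p = 5.7e-31, BH-adjusted 3.11e-30). With a fold of 1.5 or more these were 195 and 44 (12 and 4.86 expected). A further 163 genes were higher in knockout cells and lower with ICRF-193 (68.3 expected; exact p = 3.71e-26, BH-adjusted 1.86e-25), and 9 the reverse. TN day 6 and cortical neurons shared 337 lower genes (131 expected; exact p = 2.17e-67, BH-adjusted 2.17e-66; 162 at 1.5-fold, 20.2 expected) and 104 higher genes, where 104.2 were expected (exact p = 1). At 1.5-fold the higher genes shared were 33 against 11.4 expected (exact p = 5.28e-08), so the absence of an excess hangs on the fold limit. Another 385 genes were higher in knockout cells and lower with ICRF-193 (146.6 expected; exact p = 1.9e-80, BH-adjusted 2.28e-79; 184 at 1.5-fold, 32.2 expected). Both ICRF-193 experiments shared 774 lower genes (173.8 expected; 394 at 1.5-fold, 38.1 expected) and 149 higher ones (48.7 expected; 26 at 1.5-fold, 3.44 expected). TN day 2 and TN day 6 shared 254 lower and 300 higher genes (57.2 and 58.8 expected; 125 and 170 at 1.5-fold, 7.68 and 22.5 expected). Over all genes, which are not independent, the fold changes of TN day 2 and TN day 6 correlated with Pearson's r 0.354 (Spearman's rho 0.238). Those of both ICRF-193 experiments correlated with r 0.540 (rho 0.495) and those of TN day 6 with ICRF-193 at TN day 5 with r 0.165 (rho 0.0191), among 15 pairs computed.

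A set of 124 genes was lower in knockout cells at TN day 2 and TN day 6 and after ICRF-193 at TN day 5 and in cortical neurons, where 0.498 would be expected from independent calls. Of the 123 with a span, 117 were longer than 100 kb, and the median span was 501.8 kb. They include Nrg3, Dcc, Cdh13, Grik2 and Syt1. The genes higher in all 4 were Ccng1, a p53 target, and Insyn2a, chosen here after their values were seen; 0.144 were expected. At TN day 5 the call for Ccng1 (0.46) ended without DMSO replicate 1 (adjusted p = 0.195) or ICRF-193 replicate 1 (0.165). It also ended with only the arrays compared (adjusted p = 0.285), with median centring (0.0737) and with array weights (0.11).

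The effects of ICRF-193 at TN day 5 and of the knockout at TN day 6 were compared by a test of their difference. The difference passed in 1410 genes, 376 positive and 1034 negative, and 203 and 1236 with each array centred on its median. In opposite directions 172 genes were called, 163 of them lower with ICRF-193 and 18 of these from the cell cycle list. Top2a, Sox2 and Mcm3 were among the genes higher in knockout cells and lower with the drug. The count was 661 without DMSO replicate 2 and 908 without ICRF-193 replicate 1. The list difference was -1.36 for cell cycle genes (adjusted p = 1.8e-42; with an estimated correlation 0.0332) and -1.38 for progenitor and radial glia genes (adjusted p = 1.6e-19; with an estimated correlation 0.0332). It was -0.39 for astrocyte genes (adjusted p = 0.0011; with an estimated correlation 0.0433). For very long genes, which fell in both, it was -0.29 (adjusted p = 0.0002; adjusted p = 0.494 with an estimated correlation). The lists of mesenchymal (-0.87), axon guidance (-0.45), ATF4 and ER stress (-0.36) and Hox genes (-0.24) also differed, but not with an estimated correlation (adjusted p from 0.314 to 0.745).

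**Figure D4:**
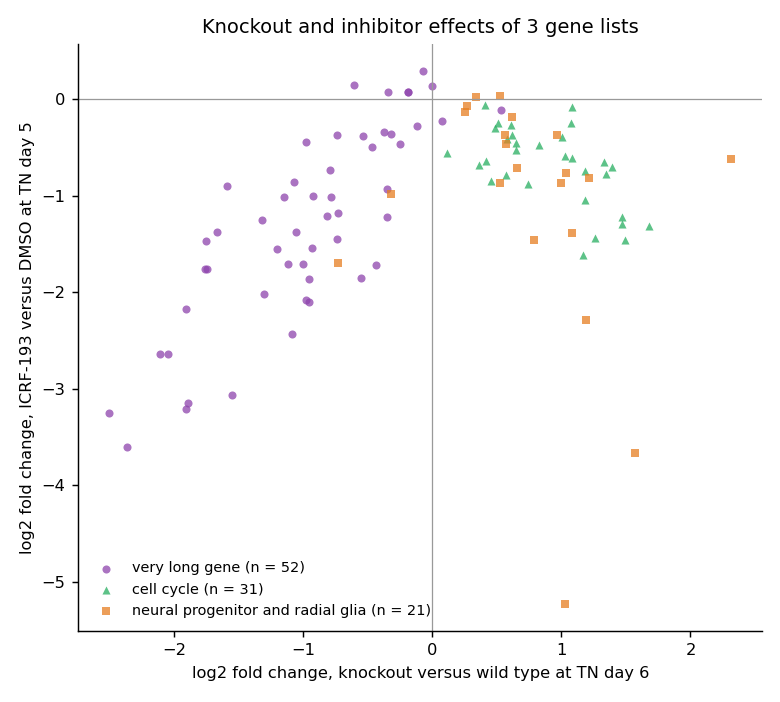
Each point is a gene of the very long (circles, n = 52), cell cycle (triangles, n = 31) or progenitor and radial glia list (squares, n = 21), placed by its log2 fold change in knockout against wild type at TN day 6 (x axis) and after ICRF-193 against DMSO at TN day 5 (y axis). Very long genes had medians of -0.94 and -1.24 on the axes, cell cycle genes 1.001 and -0.65.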

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

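The tests of partial differentiation in ES cells and of long genes matched on expression level were chosen after the result they address was seen. So were the test of the share of neurons under ICRF-193 alone and the look at genes that fell or rose as much as the cell cycle list fell. The other tests of explanations here were chosen before.

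The effect of the knockout was tested for a difference between TN day 6 and TN day 2. It differed in 957 genes, 85 of which were called in opposite directions at the 2 stages; the number was 389 without TN day 2 wild-type replicate 1 and 391 without TN day 2 knockout replicate 2. Lpl had the largest such turn among the named genes, higher by 2.61 at TN day 2 and lower at TN day 6 (difference -5.25 ± 0.26, adjusted p = 6.29e-11). The reverse turn was seen in Sfrp2 (4.43 ± 0.28, adjusted p = 3.62e-09), Gpr50 (3.75 ± 0.64, adjusted p = 0.00115), Pax6 (3.58 ± 0.37, adjusted p = 4.64e-06), Chrna5 (2.96 ± 0.30, adjusted p = 2.86e-06) and Dlx1 (1.60 ± 0.31, adjusted p = 0.00373). These differences passed in every setting, but the falls at TN day 2 of Sfrp2, Gpr50, Pax6, Chrna5 and Dlx1 were not called with only the arrays compared (adjusted p = 0.085, 0.127, 0.122, 0.0525 and 0.216). Without single arrays the highest were 0.11, 0.244, 0.24, 0.184 and 0.594. The rises at TN day 6 of Gpr50 and Dlx1 also ended without single arrays (highest 0.0577 and 0.0951). The differences for Top2a and Ngfr were 1.32 ± 0.28 (adjusted p = 0.0064) and 1.24 ± 0.18 (adjusted p = 0.000287); the fall of Ngfr at TN day 2 ended in 3 settings (highest adjusted p = 0.188). Among the lists, the median difference was 1.17 for progenitor and radial glia, 0.38 for pan-neuronal, 0.39 for cell cycle, 0.23 for neurotrophin, -0.34 for very long, -0.21 for p53 target and -0.88 for mesenchymal genes. With an estimated correlation none of these 7 lists passed (adjusted p from 0.16 to 0.644).

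Between TN day 6 and ES cells the knockout effect differed in 1157 genes, 5 of them called in opposite directions. The number was 566 and 714 without ES wild-type replicates 1 and 2, and 4692 without ES knockout replicate 2. Differences were 2.01 ± 0.28 for Top2a (adjusted p = 9.53e-05), 1.51 ± 0.20 for Nefl (adjusted p = 4.62e-05), 0.97 ± 0.18 for Ngfr (adjusted p = 0.00228) and -1.36 ± 0.19 for Ntrk3 (adjusted p = 8.62e-05). The very long gene list had a difference of -1.02, which also passed with an estimated correlation (adjusted p = 0.0046). The list differences for cell cycle (1.11), glutamatergic (-0.31), adhesion (-0.74), pluripotency (0.57), progenitor and radial glia (0.71), microglia (-0.36), p53 target (0.25), axon guidance (-0.37), ion channel (-0.21) and Hox genes (-0.44) did not pass with it (adjusted p from 0.0704 to 0.494). Without ES knockout replicate 1, the ES calls of the pluripotency, Hox, microglia and cell cycle lists ended and the axon guidance list turned. Pluripotency and Hox genes differed between replicates 1 and 2 by medians of -1.20 and 0.79. The list differences were not tested without that array, so a stage-dependent effect of the knockout cannot be read from these lists.

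The effect of ICRF-193 differed between cortical neurons and TN day 5 in 871 genes, 336 positive and 535 negative, or 231 and 581 with each array centred on its median and 534 and 470 without ICRF-193 replicate 2 at TN day 5. In the fit of all arrays 72 were called in opposite directions. Genes higher in cortical neurons and lower at TN day 5 were Peg10 (difference 2.67 ± 0.21), Pou3f2 (2.57 ± 0.23), Slc17a6 (2.50 ± 0.36), Fos (2.16 ± 0.25), Gfra1 (1.95 ± 0.16) and Npas4 (1.57 ± 0.18), with adjusted p-values between 3.26e-08 and 0.000107. The reverse held for Npy (-2.06 ± 0.19, adjusted p = 3.81e-07), Nr4a2 (-1.92 ± 0.37, adjusted p = 0.00251) and Ablim1 (-1.80 ± 0.23, adjusted p = 2.19e-05), and Ngfr rose at TN day 5 only (-0.76 ± 0.18, adjusted p = 0.0157). With only the arrays compared the calls at TN day 5 of Peg10, Npy and Nr4a2 ended (adjusted p = 0.128, 0.194 and 0.253), as they did without single arrays (highest 0.247, 0.0979 and 0.407). That of Peg10 also ended with quantile normalization (0.0632) and array weights (0.186), that of Nr4a2 with median centring (0.0665). The call of Gfra1 in cortical neurons ended with median centring (0.0662) and without DMSO replicate 2 (0.0528). For the named genes that turned, the difference itself passed in every setting. The effect on astrocyte genes (difference -0.74) and on oligodendrocyte lineage genes (-0.35) was lower in cortical neurons than at TN day 5, also with an estimated correlation (adjusted p = 0.00123 and 0.0196). The other list differences did not pass with it (adjusted p from 0.446 to 0.748). They were -0.49 for cell cycle, -0.38 for ion channel, -0.16 for pan-neuronal, -0.13 for very long, -0.0542 for GABAergic, 0.16 for progenitor and radial glia, 0.28 for immediate early, 0.30 for Hox, 0.35 for microglia and 0.63 for mesenchymal genes.

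The first pattern weighed is that ES knockout replicate 1 stood apart from replicate 2, with mesenchymal genes higher in it by a median of 1.64 (16 of 16), early mesoderm genes by 1.02 (11 of 11) and Mixl1 by 4.37. A weaker hybridization is argued against, since the difference between both arrays did not follow expression level (Spearman's rho 0.0511 across genes). That value says nothing of random noise, but noise would not move nearly all genes of a list 1 way. Partial differentiation of that culture may explain it: 24 of 25 pluripotency genes were lower in replicate 1, with a median of -1.20. RNA of another cell population of this series stays open. Of the 200 genes most enriched in knockout NP cells, 87.5% were higher in replicate 1, against 44.9% of all genes. Differentiated ES cells would share such genes. Other lists moved otherwise than RNA of NP cells alone would move them. Progenitor and pan-neuronal genes, higher in wild-type NP than ES cells by medians of 1.09 and 0.86, differed by 0.016 (12 of 21 higher in replicate 1) and -0.32 (12 of 29). Mesenchymal genes, higher in replicate 1, were lower in NP cells by a median of 0.67. Top2b stood at 7.11 in replicate 1, 5.79 in replicate 2 and 7.53 in wild-type replicate 2, so RNA of wild-type cells also stays open. The Top2b mean of 6.83 in knockout NP cells leaves differentiation open as the source too. The knockout itself was not tested as an explanation, since replicate 2 is the only other array of that group.

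The second pattern is that long genes were lower at TN day 6 and after ICRF-193. After ICRF-193 their expression level may account for part of the trend over all genes, since given the control level rho moved from -0.187 to -0.0636 at TN day 5 and from -0.191 to -0.0778 in cortical neurons, and what is left cannot be told apart from an uneven correction. At TN day 6 rho was 0.0349, 0.0463 given the control level and -0.0400 with dim genes removed, so its sign hangs on dim genes and the part of level stays open there. For genes over 300 kb the level is argued against as the whole cause: at least 86.7% of their difference from genes up to 100 kb was left after matching on level. A lower share of neurons in the cultures predicts that short neuronal genes fall too; at TN day 6 the median was -0.0485 for short and -0.22 for long neuronal genes. For the knockout this stays open, because the median of the long ones did not reach the fall set beforehand. For ICRF-193 alone, the same medians were looked at afterwards in a separate test, on the values as deposited. The medians of long neuronal genes were -0.46 at TN day 5 and -0.49 in cortical neurons. Those of short ones were -0.0590, the lowest of the 3 comparisons, and 0.0353. That test kept the limits of the planned one and left out the knockout after it had missed them, so its outcome was known beforehand. It therefore cannot decide on the share of neurons. The values show only that long neuronal genes were lower than short ones in both experiments. The test was not repeated with median centring, which moved the median of all genes at TN day 5 by -0.0646. A shift of that size would matter for a short-gene median of -0.0590. An effect of the loss of Top2β or of ICRF-193, the differences the design names, stays open and was not tested apart from these explanations.

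The third pattern is that cell cycle genes were higher in knockout cells at TN day 6 and lower after ICRF-193. More progenitor cells in the knockout culture may explain the first part, since the progenitor and radial glia list had a median of 0.66 there. Loss of progenitor cells under ICRF-193 may explain the second part. The medians of that list were then -0.77 at TN day 5 and -0.48 in cortical neurons. Its call in cortical neurons ended with an estimated correlation and with quantile normalization (camera adjusted p = 0.0779). Astrocyte genes fell further in these neurons, so the fall was not limited to progenitor genes. Neither test tells dividing progenitors from a change within each cell. Slower maturation of the knockout culture stays open. Genes that rose between TN day 2 and TN day 5 had a median of -0.0419 in knockout cells. The rule set beforehand counted so small a fall against this explanation. Genes that fell over that time had a median of 0.0766 in knockout cells, short of the rise set beforehand. The median change of the rising genes between these days was only 0.53, against -1.39 for the cell cycle list. Strongly changed genes were therefore looked at afterwards. Of 222 other genes that fell as much as that list did, 90.5% were higher in knockout cells, with a median of 0.57. Of 81 genes that rose at least as much, 74.1% were lower in knockout cells, with a median of -0.18. The 222 genes leave out only the listed cell cycle genes, so they can still hold other genes of dividing or progenitor cells. Their rise cannot tell slower maturation from more progenitor cells. Both sets were chosen after the planned result was seen.

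For both comparisons of 3 against 3 arrays, the 10 possible splits are too few for a share under 0.05. At TN day 6 the real split called 2030 genes and the highest of the others 0; 1 of 10 splits called as many. In cortical neurons the real split called 4664 genes and the highest of the others 0; again 1 of 10 called as many.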

How the results depend on the processing

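The alternatives were fixed before the values were seen, except the crossed replicate block in NP cells. Over the named genes with a call, every call was kept with the filter on dim genes among genes that passed it (371 of 371), and 381 of 399 were kept with quantile normalization, 375 with median centring, 394 with trend and robust estimation, 397 with the mean over probe sets, 363 with array weights and 301 with only the arrays compared. With single arrays left out 1616 of 1958 were kept, and 0 of these turned in direction. Of 67 list calls 59 were kept with quantile normalization, 65 with only the arrays compared, 47 with fry and 8 with an estimated correlation, and with single arrays left out 276 of 316 were kept, 35 ended and 5 turned.

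With only the arrays compared the number of calls was 0 in ES cells, 201 in NP cells, 315 at TN day 2, 385 at TN day 5 and 7960 in cortical neurons, and 474 for the difference between TN day 6 and ES cells. With array weights it was 0 in ES cells, 251 in NP cells, 3816 at TN day 6, 742 at TN day 5, 8967 in cortical neurons, 1555 for the difference between TN day 6 and TN day 2 and 280 for that between TN day 6 and ES cells. Both settings change how a gene's spread is estimated. The fit of all arrays pools it over all 12 groups. Among groups of 2, the median SD ran from 0.062 in knockout NP cells to 0.171 in knockout ES cells. Array weights were 0.162 for both knockout ES arrays, 0.487 for both ICRF-193 arrays at TN day 5 and 1.61 to 2.01 in cortical neurons. A pooled spread is too small for noisier groups and too large for others. How much of each shift this explains was not tested. limma found 2995 genes at an unadjusted p under 0.05 in ES cells in the fit of all arrays.

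With an estimated correlation the number of lists past the threshold was 0 in ES cells, 1 in NP cells, 0 at TN day 2, 2 at TN day 6, 2 at TN day 5 and 3 in cortical neurons, and with fry 3 in ES and 4 in NP cells; the cause was not tested.

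A fold of 1.5 or more counts fewer genes by construction. Shared lower genes were then 125 for TN days 2 and 6 (7.68 expected), 195 for TN day 6 and ICRF-193 at TN day 5 (12), 162 for TN day 6 and cortical neurons (20.2) and 394 for both ICRF-193 experiments (38.1). Shared higher genes were 170, 44, 33 and 26 (22.5, 4.86, 11.4 and 3.44 expected), and 184 were higher at TN day 6 and lower in cortical neurons (32.2). The 33 are an excess that the 104 shared without a fold limit are not; the cause was not tested. At a span limit of 200 kb the odds ratio of long genes among lower calls in ES cells was 0.79. Among higher calls it was 0.827 in ES cells with dim genes removed (exact p = 1) and 1.83 in NP cells (exact p = 0.0616). At 200 kb it was 1.27 at TN day 6 (exact p = 0.113), 1.28 at TN day 5 (exact p = 0.257) and 1.11 in cortical neurons (exact p = 0.459), while it stayed at 1.96 at TN day 2 (exact p = 7.97e-07) and 3.10 in NP cells (exact p = 0.00283). Further, with dim genes removed the correlation with span was 0.0553 in ES cells, 0.0168 in NP cells and -0.0294 at TN day 2. It was -0.0400 at TN day 6, -0.117 at TN day 5 and -0.0879 in cortical neurons. The cause of these shifts was not tested.

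With single arrays left out, the number of calls ran from 5 to 5018 in ES cells, from 37 to 72 in NP cells, from 504 to 2364 at TN day 2 and from 684 to 2291 at TN day 5. It ran from 389 to 1425 for the difference between TN days 6 and 2, from 566 to 4692 for that between TN day 6 and ES cells and from 661 to 1817 for that between ICRF-193 at TN day 5 and the knockout at TN day 6. The lists past the threshold in ES cells were 5 to 12. Adjusted p-values in ES cells ran from 1.52e-12 to 0.218 for pluripotency, 0.00499 to 0.676 for endothelial, 5e-07 to 0.387 for mesenchymal, 1.21e-07 to 0.0181 for early mesoderm and 2.62e-08 to 0.00737 for axon guidance genes; all 5 turned without ES knockout replicate 1 (0.218, 0.676, 0.387, 0.00201 and 0.00209). That array stands apart from its partner; why was not settled.

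With replicate number as a block the calls were 54, 110, 2214, 1988, 1586 and 4555 in the order of the comparisons, and 121 in NP cells with the crossed block. The block kept 377 of 399 calls of named genes and 66 of 67 list calls, and the crossed block 28 of 32 calls of named genes. Deviations of same-numbered arrays correlated at 0.379 at TN day 5 and 0.137 at TN day 2, at 0.0385 in ES and -0.23 in NP cells, and between -0.0616 and 0.0709 in both comparisons of 3 against 3. The labels do not say that a number pairs samples, and for TN day 5 and TN day 2 pairing stays open.

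Signal over background was not given for the arrays, so small changes of dim genes cannot be told from background. Whether the differences between ES or NP arrays and later ones also hold a difference between array batches was not tested, since no label names a batch.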

Other observations

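The receptor genes Ntrk2 and Ntrk3 fell after ICRF-193, Ntrk2 by 1.33 and Ntrk3 by 1.62 at TN day 5, and Ntrk2 by 2.14 and Ntrk3 by 1.75 in cortical neurons, while Ntrk2 was not called in knockout cells at any stage. Its change was -0.36 ± 0.21 at TN day 2 (adjusted p = 0.339) and -0.32 ± 0.17 at TN day 6 (adjusted p = 0.324). Every knockout array lay below every wild-type array in NP cells, at TN day 2 and at TN day 6. At TN day 6 the arrays stood at 8.56, 8.60 and 8.56 in wild-type and 8.20, 8.32 and 8.24 in knockout cells. The SE of 0.17 pools the spread of all 12 groups, among them DMSO at TN day 5 with 8.67 and 9.26. The missing call at TN day 6 therefore does not show that Ntrk2 was unchanged in knockout cells. The effect of ICRF-193 on Ntrk2 at TN day 5 minus that of the knockout at TN day 6 was -1.004 ± 0.27 (adjusted p = 0.0279).

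A set of 218 genes was lower in knockout cells at TN day 6 and in both ICRF-193 experiments, where 8.35 would be expected from independent calls. Of the 217 with a span 184 were longer than 100 kb, with a median of 417 kb. Another 33 genes were higher in all 3, where 2.62 would be expected, and 3 of the 32 with a span were that long.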
